A study of Mus musculus with 18 samples.

How the data were processed

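Liver RNA of 18 male C57BL/6 mice was sequenced, 6 each from Control, Cirrhosis and Cirrhosis-PTH. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed and libraries were made with a NEBNext RNA kit. A step that digests linear RNA is not named there. Groups and replicate numbers were taken from the sample titles. The labels name 6 mice per group, so each library is 1 mouse, and they give no sequencing batch or date.

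The deposited values are CPM of circRNAs, made by the authors, with 1 line per circRNA and 1 column per library. Per the submitters' processing notes, the tools were HISAT2 2.2.1, StringTie 2.1.5, cutadapt 4.2, Bowtie 1.3.1, Bowtie2 and Trim Galore, with the genome build GRCm38 and no role given for each. The caller of the back-splice junctions was CIRI, per the file headers, and its version is not given in the sources used here. What the CPM is scaled to is not given either. The summed CPM of the listed circRNAs was 99.5 to 435 per library, so the listed circRNAs were a small part of it. Each listed circRNA was above 0 in 9 or more of the 18 libraries, so circRNAs seen in fewer were not analysed here.

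All values of a library were whole multiples of the CPM of 1 read. Of the 5886 values above 0, 100% came out as whole reads within 0.01, with a largest deviation of 0.0016. These steps gave the recovered reads (794 to 8431 per library, 38784 in all) and the total behind the CPM (2706146 in Control 1 to 29164326 in Cirrhosis-PTH 6). A single read was worth 0.0343 to 0.370 CPM, and a library's floor of 3 reads lay at 0.103 to 1.11 CPM. Back-splice reads are counted without molecular identifiers, so floors and intervals cover counting error only. The median SE of a fitted log2 difference was 0.694. Replicate pairs differed by more than counting noise in all 45 pairs (chi-square per degree of freedom 2.11 to 5.85), so no library was counted as a duplicate.

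Each circRNA's ends were compared with the exon ends of the GENCODE M21 annotation of GRCm38. Positions are 1-based, and exons are numbered along the transcript that holds both ends. The deposited table gives no strand, so strand was taken from the annotated host gene. List members are counted as higher or lower by the sign of the fitted log2 difference. Values of list members are of the host's most abundant circRNA unless exons or a position are given.

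The main test was limma 3.58.1 in R 4.3.3 (with the trend option) on log2(CPM + 0.143), with 1 model of all 18 libraries, a 2-sided test for each of 3 comparisons and Benjamini-Hochberg adjustment over 474 circRNAs at 0.05. The pseudocount was the median over libraries of the smallest value above 0. A filter of above 0 in at least 6 libraries removed 0 circRNAs. Median centring, 1 of the other settings below, subtracted each library's median log2 value over the 26 circRNAs above 0 in all 18 libraries. The distance tests after centring used the same median. Host-gene lists with 3 or more measured circRNAs were tested with limma's camera at a preset correlation of 0.01, adjusted over 13 lists in each comparison, and again with an estimated correlation. The lists were lipid, amino acid and urea cycle, carbohydrate and xenobiotic metabolism, bile acid metabolism and hepatobiliary transport, secreted plasma proteins, extracellular matrix and fibrosis, TGF-beta, Wnt, Hippo and growth factor signalling, cell cycle and DNA replication, chromatin regulators, ubiquitin ligases and deubiquitinases, widely studied circRNA hosts, and markers of hepatocytes, stellate cells and myofibroblasts, liver endothelial cells, macrophages and Kupffer cells, lymphocytes, cholangiocytes and progenitors, and erythroid cells.

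Library measures were compared with exact 2-sided permutation tests. The p values of the macrophage-list sums and shares were not adjusted over the 3 pairs. Profiles were compared by the mean Euclidean distance between groups minus that within groups, with an exact 1-sided permutation test over all splits, whose smallest p is 0.00216. The correlation of the differences of Cirrhosis against Control with those of Cirrhosis-PTH against Cirrhosis was set beside 1000 simulated draws with no effect and repeated with the Cirrhosis libraries split into 3 and 3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 was used for these, and matplotlib 3.10.9 for the figures.

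The groups, tests, lists, other settings to try and the rule for named circRNAs were set before the data were examined. By that rule, with fewer than 5 circRNAs past the threshold in a comparison, those that passed and the 6 with the smallest p were named, together with the 10 of highest mean CPM and, in each list without a passing member, up to 3 of highest mean CPM. Some circRNAs that the rule names are not reported here. Names outside the rule are stated as chosen after their values were seen.

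Other settings listed then were other pseudocounts (0.0714 CPM, 0.571 CPM and 1 CPM), a filter of 12 libraries, quantile normalization, median centring, no trend, library weights, a fit of 2 groups only, a term for the number in the sample title, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 on the recovered reads, 1 circRNA per host in the list tests, the Spearman distance and each library left out in turn. Added after the data were seen were edgeR with the totals behind the CPM, Cirrhosis 6 and Cirrhosis-PTH 4 left out together, thinning to 794 reads, other scalings and left-out libraries for the list tests, other scalings, pseudocounts and statistics for the distance, left-out libraries for group means, pooled ratios and bounds against a floor, other splits in edgeR, and a test of the numbers in the titles.

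The limma, edgeR and camera steps were tested on simulated data with known changes, for limma and edgeR 10 simulations of 474 circRNAs with 200 changed. In the layout of Cirrhosis against Control, limma recovered 24% of the changes of 4-fold and 42.4% of those of 8-fold, with 2.64% false calls. In that of Cirrhosis-PTH against Cirrhosis it recovered 21.9% at 4-fold and 46.9% at 8-fold, with 2.27% false. In that of Cirrhosis-PTH against Control it recovered 17.3% and 42.9%, with 2.75% false. The edgeR test recovered 20.5%, 24.1% and 21.1% at 4-fold and 45.8%, 58.4% and 58% at 8-fold in the same order. With 200 of 474 circRNAs changed the adjustment is more lenient than where few change. A single call among 474 needs an unadjusted p of 0.000105 in limma. Recovery with few changed circRNAs was not simulated and would be lower. Camera found 9, 10 and 10 of 10 lists of 3 circRNAs raised 4-fold, and called 0, 1 and 1 of 10 unchanged lists. The simulated circRNAs were drawn independently, while the macrophage list of the data had an estimated correlation of 0.399. False calls for such a correlated list were not simulated. In the layout of 6 against 6 libraries, the distance test called 2 of 20 unchanged data sets and 20 of 20 with 60 circRNAs shifted, and the exact permutation test called 5.5% of 200 unchanged measures and 100% of 50 shifted by 3 SD. DESeq2, the thinned distance and the tests of exon starts, introns and shared hosts were not tested on simulated data.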

Results

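Circular RNAs (circRNAs), closed RNA molecules formed when the 3' end of an exon is joined to the 5' end of the same or an upstream exon, were measured by RNA sequencing of liver from 18 male C57BL/6 mice, 6 in each of 3 groups. The Control group received corn oil by intraperitoneal injection and distilled water by mouth. The Cirrhosis group received 10% carbon tetrachloride (CCl4), a liver toxin, in corn oil and the same water. The Cirrhosis-PTH group received 10% CCl4 and oral Pien Tze Huang (PTH), a Chinese patent medicine, at 0.25 mg per g of body weight a day. Injections of 10 µl per g were given 2 times a week, and livers were taken after 12 weeks. The labels describe treatment of 45 mice, 15 per group, and sequencing of 18.

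The deposited table held 474 circRNAs of 417 host genes, each in library-scaled read counts (CPM), and each above 0 in at least 9 of the 18 libraries. On GRCm38, 440 of the 474 had both ends at annotated exon ends of 1 gene and 26 had 1 end there. Of the circRNAs placed in 1 transcript, 417 held several exons and 18 a single exon, with a median of 3 exons and 306 bp. The exons were coding in 361 circRNAs and spanned 5' UTR and coding sequence in 56. Protein-coding genes hosted 459 circRNAs. At 48 hosts 2 or more circRNAs were listed, 105 in all, with 4 from Etv6.

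Depth was low. The values corresponded to 38784 back-splice reads, from 794 in Control 1 to 8431 in Cirrhosis-PTH 6, with a median of 2 reads per circRNA and library. Of all values, 31.0% were 0, 43.3% were 0 or 1 read and 12.4% were 10 reads or more. Of 175 group means above 0, from the 59 circRNAs looked at singly, 52 moved by over 1.5 times without the highest library of the group. Among those given below they include the Control means of Rock1, Snx5, Adgre1, Acvr2a, Elovl5, Acaca and Gbe1 and the Cirrhosis-PTH means of Adgre1 (exons 6 to 7), Ascc3, Etv6, Pabpn1 and Tasp1. The circRNAs detected per library were 328 ± 44.3 in Control, 325 ± 59.6 in Cirrhosis and 328 ± 55.2 in Cirrhosis-PTH (mean ± SD, n = 6 each), and 26 circRNAs were detected in all 18. The exact permutation tests between groups gave adjusted p values of 1.0 for all 3 pairs. Cirrhosis 6 had the fewest detected circRNAs, 223, from 2218 reads. Summed CPM was 259 ± 91.9 in Control, 327 ± 96.6 in Cirrhosis and 247 ± 87.9 in Cirrhosis-PTH, with exact permutation p values, adjusted over 3 pairs, of 0.36 for Cirrhosis against Control, 0.36 for Cirrhosis-PTH against Cirrhosis and 0.823 for Cirrhosis-PTH against Control.

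**Figure D1:**
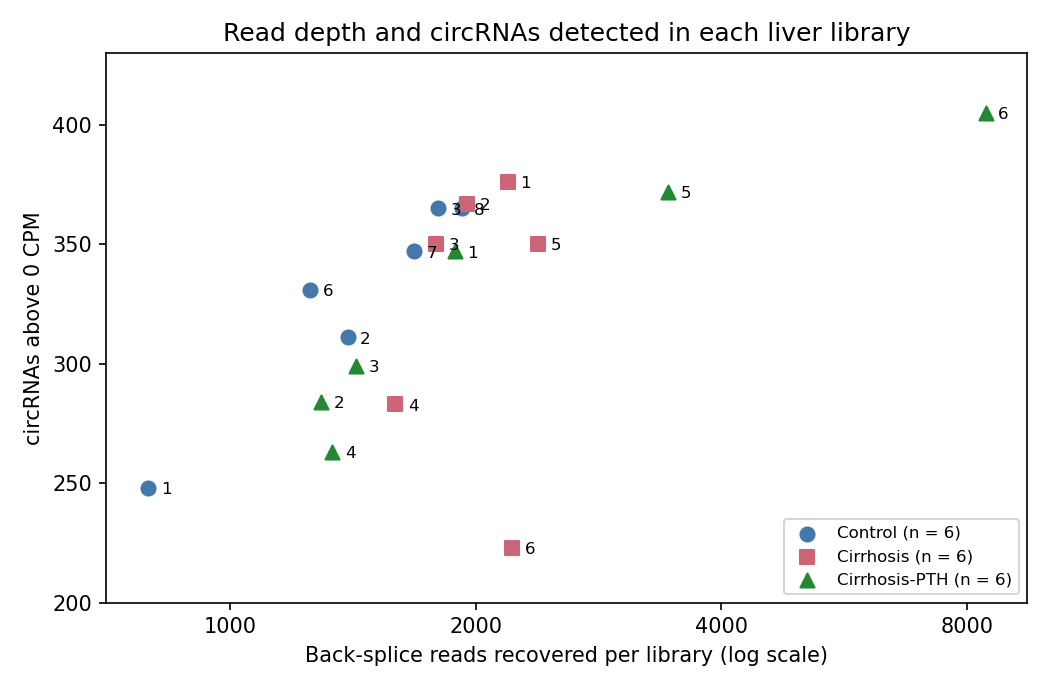
Back-splice reads recovered per library (x axis, log scale) against the number of circRNAs above 0 CPM (y axis) for 6 Control, 6 Cirrhosis and 6 Cirrhosis-PTH libraries, each point 1 library with its number. Cirrhosis-PTH 6 lies farthest right at 8431 reads, and Cirrhosis 6 lies lowest, with 223 circRNAs from 2218 reads.

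The circRNA with the highest mean CPM came from Ube3a, which encodes a ubiquitin ligase (chromosome 7, 59240967 to 59247217, exons 2 to 4, 5' UTR and coding), at 5.44 ± 3.18 CPM in Control, 6.78 ± 2.31 in Cirrhosis and 7.98 ± 4.2 in Cirrhosis-PTH. It was followed by circRNAs of Rmdn2 (chromosome 17, 79650302 to 79659473, coding exons 3 to 5), at 7.0 ± 3.18, 8.09 ± 3.79 and 5.01 ± 2.43 CPM, and of the sterol transfer protein gene Gramd1c (chromosome 16, 44028679 to 44040158, coding exons 3 to 6), at 4.42 ± 1.2, 5.80 ± 2.26 and 6.47 ± 3.21 CPM in the same order. The other 7 of the 10 most abundant came from Erbin, the mannosyltransferase gene Alg12, Tmem56, Eed, Ttc39c, Pvt1 and the oxoglutarate dehydrogenase gene Ogdh. The 10 took 16.2 ± 1.56% of recovered reads in Control, 16.8 ± 2.71% in Cirrhosis and 17.9 ± 1.62% in Cirrhosis-PTH.

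Cirrhosis was compared with Control to ask what CCl4 changed in the circRNA profile. The circRNAs that differed with the smallest p were higher in Cirrhosis and came from genes of several functions. That of Rock1, which encodes a kinase that acts on the actin cytoskeleton, stood at 0.190 ± 0.247 CPM in Control and 2.08 ± 2.27 in Cirrhosis (mean ± SD, n = 6; 1.17 in Cirrhosis without Cirrhosis 6). That of Rasa2, a Ras GTPase-activating protein gene, stood at 0.623 ± 0.460 and 2.89 ± 1.03 CPM, and that of Eed, a core subunit gene of Polycomb repressive complex 2, at 1.46 ± 1.0 and 5.0 ± 2.35 CPM. A circRNA of Adgre1, which encodes the macrophage surface protein F4/80, stood at 0.157 ± 0.253 and 1.5 ± 1.38 CPM. The single-exon circRNA of the long non-coding RNA Pvt1 stood at 1.15 ± 0.440 and 5.60 ± 4.11 CPM.

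No single circRNA passed limma's test at an adjusted p of 0.05 in this comparison, against 58 with an unadjusted p under 0.05 (42 higher and 16 lower in Cirrhosis, 23.7 in all by chance). On the read counts recovered from the CPM, edgeR also called 0, with 29 under an unadjusted 0.05, and DESeq2 called 1, with 38. The DESeq2 call was Ube2g2, a ubiquitin-conjugating enzyme gene (chromosome 10, 77630726 to 77630894, coding exons 2 to 3), chosen after its values were seen. It stood at 1.85 ± 0.816 CPM in Control and 0.431 ± 0.468 in Cirrhosis (0.262 without Cirrhosis 5). It lay below the Control mean in 6 of 6 libraries, with an adjusted p of 0.0249 in DESeq2. DESeq2 scaled the libraries on the 26 circRNAs detected in all 18. The median centring below, which called Ube2g2 too, used the same 26, so both calls rest on them.

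On the log2(CPM + 0.143) scale, which understates the change of low circRNAs, the fitted differences (± SE) had adjusted p values of 0.109 or more in limma. The Rock1 circRNA (chromosome 18, 10129305 to 10132272, coding exons 7 to 9, 376 bp) differed by 2.63 ± 0.71, with limma's adjusted p = 0.109, and lay above the Control mean in 6 of 6 Cirrhosis libraries. The Rasa2 circRNA (chromosome 9, 96602713 to 96611499, coding exons 2 to 4, 317 bp) differed by 2.28 ± 0.65 (limma adjusted p = 0.109), above the Control mean in 6 of 6. It alone had every Cirrhosis library above every Control library, where chance gives 0.216% of circRNAs or 1.03 of 474. The circRNA of Eed (chromosome 7, 89955531 to 89962361, coding exons 9 to 11, 339 bp) differed by 1.80 ± 0.55, that of the sorting nexin gene Snx5 (chromosome 2, 144255340 to 144257993, coding exons 5 to 8, 402 bp) by 2.40 ± 0.73, and that of Adgre1 (chromosome 17, 57419322 to 57420524, coding exons 11 to 12, 262 bp) by 2.37 ± 0.73. These 3 had an adjusted p of 0.119 each in limma and lay above the Control mean in 6 of 6 libraries, for Adgre1 in Cirrhosis 6 by a single read (0.184 CPM). Snx5 stood at 0.173 ± 0.233 CPM in Control and 1.37 ± 0.788 in Cirrhosis. The Pvt1 circRNA (chromosome 15, 62107148 to 62107465, exon 2 of a non-coding transcript, 318 bp) differed by 1.81 ± 0.59, with limma's adjusted p = 0.157, above the Control mean in 5 of 6 libraries.

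Over all 474 circRNAs the median log2 difference was 0.12, with 56.1% higher in Cirrhosis. Centring each library on the median of the 26 circRNAs detected in all 18 moved these to -0.46 and 28.9%. It brought Hnrnpu and Ube2g2 past the threshold in limma (smallest adjusted p 0.0272, against 0.0249 to 0.412 over 15 alternatives). Both were named after their values were seen and lay below the Control mean in 5 and 6 of 6 Cirrhosis libraries. The direction of the whole profile, and with it the numbers of higher and lower list members, followed the scaling. The differences of the circRNAs of smallest p kept their sign under every alternative run. That says little, since these circRNAs were picked for small p in the same libraries.

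**Figure D2:**
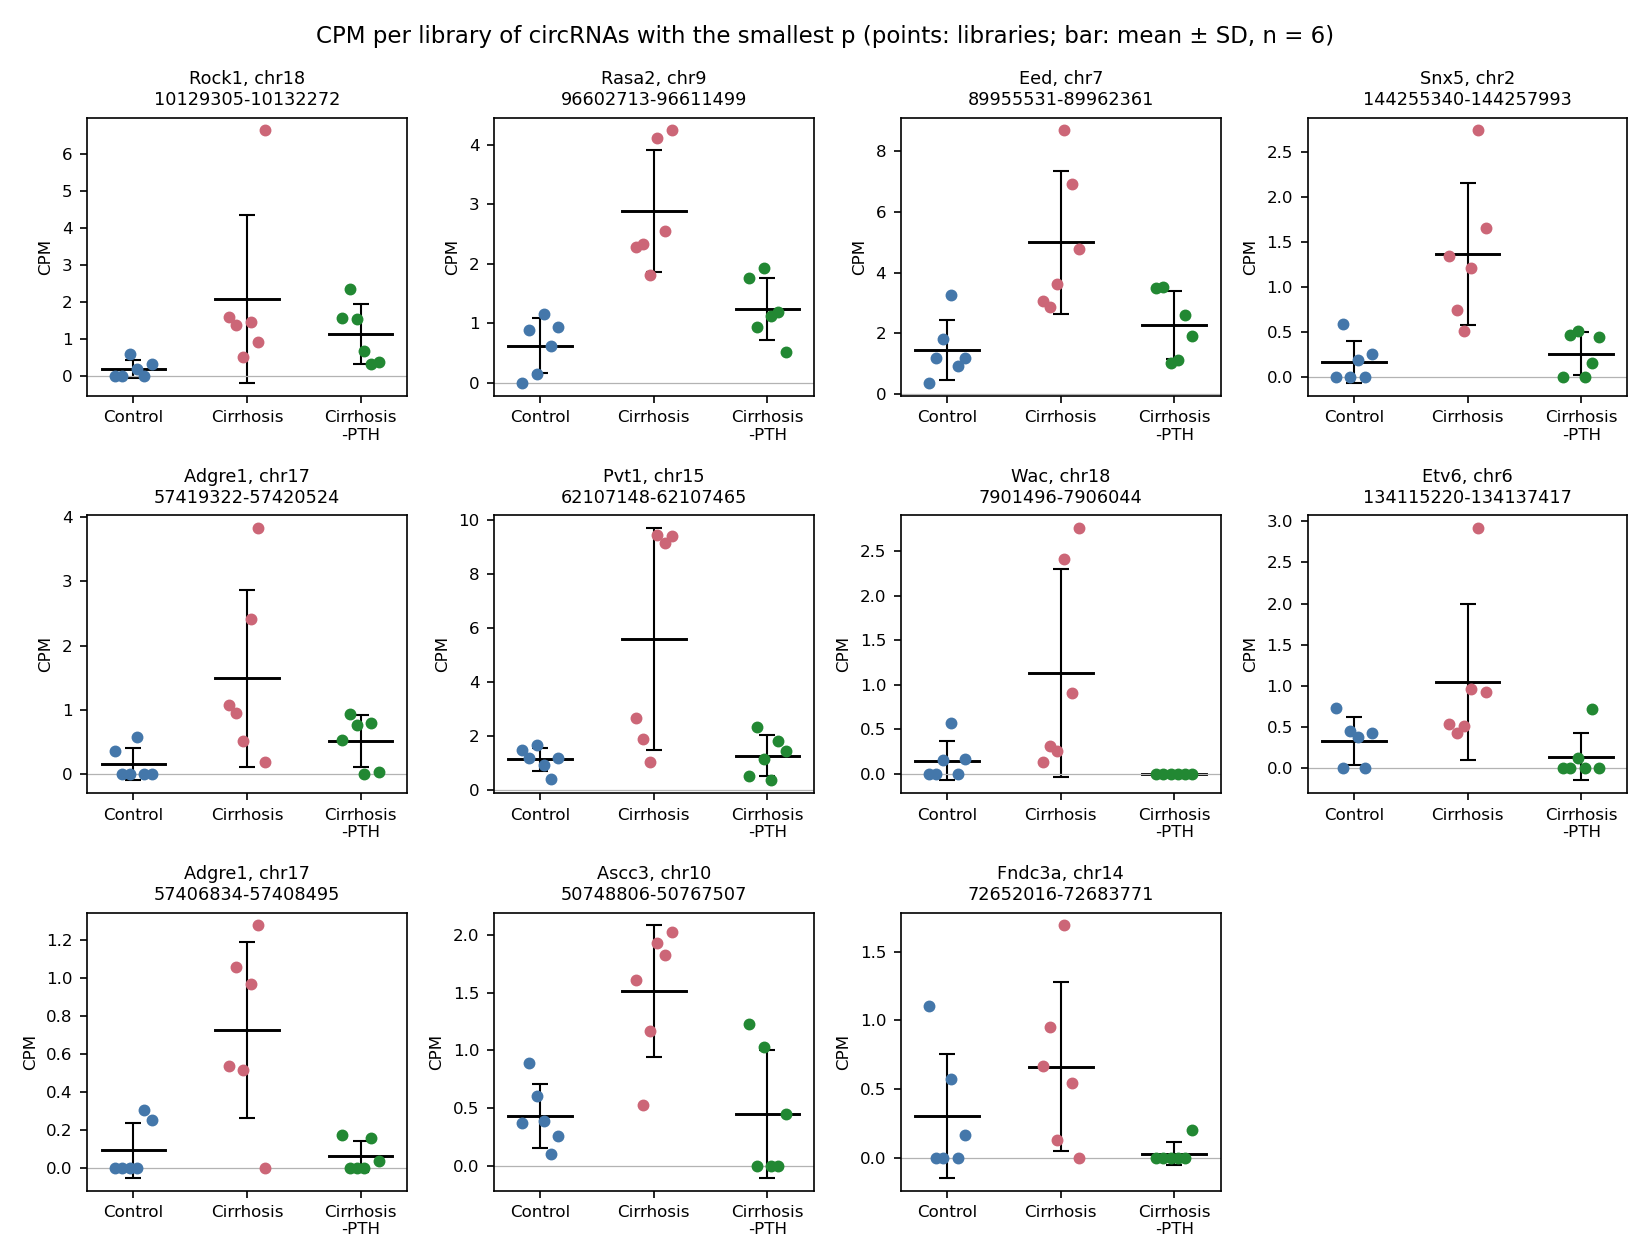
CPM (y axis) of the 11 circRNAs with the smallest p in Cirrhosis against Control or Cirrhosis-PTH against Cirrhosis, 1 panel each titled with host gene and GRCm38 position, in Control, Cirrhosis and Cirrhosis-PTH (x axis). Points are libraries and bars are mean ± SD (n = 6). Wac lies at 0 in all 6 Cirrhosis-PTH libraries, and Rasa2 is higher in every Cirrhosis library than in every Control library.

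Of the 19 host-gene lists fixed beforehand, 13 had at least 3 measured circRNAs and 1 passed limma's camera test in Cirrhosis against Control. The macrophage and Kupffer cell list had 3 circRNAs, all higher in Cirrhosis, with camera's adjusted p = 0.0203. The call was lost with an estimated correlation (adjusted p = 0.388). It was also lost with the title number as replicate block, on the 4 shared numbers (camera adjusted p = 0.13). Besides the Adgre1 circRNA above, a second one from Adgre1 (chromosome 17, 57406834 to 57408495, coding exons 6 to 7, 297 bp) stood at 0.093 ± 0.146 CPM in Control and 0.727 ± 0.465 in Cirrhosis, above the Control mean in 5 of 6 libraries. That of Mertk, a receptor gene for the uptake of dying cells (chromosome 2, 128736563 to 128738369, coding exons 3 to 4), stood at 0.294 ± 0.303 and 0.843 ± 0.648 CPM. In limma 0 of the 3 passed over all circRNAs tested, while both Adgre1 circRNAs passed adjusted over the list alone (adjusted p = 0.00375 and 0.0104). Cirrhosis 6 had 1 read of the 3, 0.184 CPM, below 5 of 6 Control libraries. The 3 together summed to 0.545 ± 0.348 CPM in Control and 3.07 ± 2.34 in Cirrhosis, from 25 and 115 reads (exact permutation p = 0.013, 2-sided, chosen after the camera call was seen). The camera call ended without Control 2, Cirrhosis 2, Cirrhosis 4 or Cirrhosis 5, each left out alone in a check added after the call was seen (adjusted p = 0.0918, 0.068, 0.0511 and 0.0845).

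No other list passed camera in this comparison, and no member of any list passed limma over all circRNAs tested. In the signalling list of TGF-beta, Wnt, Hippo and growth factor genes, 6 of 10 were higher, and Rock1 passed adjusted over the list alone (limma adjusted p = 0.00231). In that list the circRNA of the receptor gene Acvr2a stood at 0.481 ± 0.560 CPM in Control and 1.01 ± 0.840 in Cirrhosis. That of the receptor gene Egfr, also a hepatocyte marker, is counted as higher by its fitted log2 difference of 0.50, while its mean CPM was lower, 1.53 ± 1.65 in Control and 1.23 ± 0.818 in Cirrhosis. Of 16 circRNAs from chromatin regulators 8 were higher, and Eed passed adjusted over the list alone (limma adjusted p = 0.0156). Med13l, a Mediator kinase module gene, stood at 1.93 ± 0.325 and 2.92 ± 1.28 CPM. Of 5 cell cycle and DNA replication circRNAs 4 were higher. The circRNA of the primase subunit gene Prim2 (chromosome 1, 33628395 to 33630433, coding exons 6 to 7), named after its values were seen, passed adjusted over that list alone (limma adjusted p = 0.0191). It had 0 reads in Control and 21 in Cirrhosis, at least 6.97-fold higher against a floor of 3 reads over the Control group. That bound takes the 21 Cirrhosis reads as exact, and was 4.89-fold without Control 8.

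The metabolic lists were divided. Of 12 lipid metabolism circRNAs 7 were higher in Cirrhosis, among them that of the fatty acid elongase gene Elovl5 at 0.122 ± 0.161 CPM in Control and 1.14 ± 0.964 in Cirrhosis, and that of Acaca, the gene of the enzyme for the first committed step of fatty acid synthesis, at 0.276 ± 0.327 and 0.680 ± 0.491. Of 8 amino acid and urea cycle circRNAs 3 were higher. Bckdhb, which encodes a subunit of the branched-chain ketoacid dehydrogenase, had a pair of them, at 1.35 ± 0.772 and 3.41 ± 2.16 CPM (coding exons 4 to 8) and at 0.985 ± 0.647 and 3.48 ± 4.42 CPM (exons 2 to 6). Cirrhosis 6 alone stood at 12.4 CPM for the latter, and the Cirrhosis mean without it was 1.7 CPM. Carbohydrate metabolism had 4 of 7 higher, with Ogdh at 3.14 ± 1.52 and 2.92 ± 1.71 CPM and the glycogen branching enzyme gene Gbe1 at 0.958 ± 0.863 and 1.09 ± 0.585. Xenobiotic metabolism had 3 of 7 higher, and the circRNAs of Ces1c, Cyp3a25 and Cyp2c70 lie in families of near-identical genes, which leaves their assignment uncertain. Bile acid and hepatobiliary transport had 2 of 5 higher, with the bile salt export pump gene Abcb11 at 0.297 ± 0.278 and 0.341 ± 0.378 CPM (0.216 in Cirrhosis without Cirrhosis 4). Secreted plasma proteins had 2 of 4 higher, ubiquitin ligases and deubiquitinases 8 of 12, widely studied circRNA hosts 17 of 31 and hepatocyte markers 2 of 3. The camera adjusted p of these 12 lists ran from 0.605 to 0.917. For chromatin regulators the median (0.06) and mean (0.10) log2 difference were positive and camera's direction was down. Camera sets a list against the other circRNAs, and the median over all 474 was 0.12. For carbohydrate metabolism and for secreted plasma proteins the median (0.10 and 0.01) was positive, while the mean (-0.07 and -0.21) and camera's direction were negative.

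Lists with fewer than 3 measured circRNAs were not tested. Extracellular matrix and fibrosis had 1, from the aspartate hydroxylase gene Asph, at 1.11 ± 0.988 CPM in Control, 1.13 ± 0.680 in Cirrhosis and 1.12 ± 0.673 in Cirrhosis-PTH. Stellate cell and myofibroblast had 1, from Tmem56, at 3.53 ± 1.48, 3.74 ± 2.78 and 1.69 ± 0.345 CPM. Lymphocyte had 1, from the transcription factor gene Ikzf1, at 0.514 ± 0.351, 0.901 ± 1.03 and 0.373 ± 0.321 CPM. Liver endothelial, cholangiocyte and erythroid markers had 0 measured circRNAs.

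The whole profiles of Cirrhosis and Control lay farther apart than libraries of 1 group did, by a mean Euclidean distance of 1.47 (37.6 between and 36.1 within groups; exact permutation p = 0.00216, 1-sided, the smallest that the splits can give, 0.00325 adjusted over 3 pairs). Leaving out Control 1, Control 2 or Control 7 ended the call (exact permutation p = 0.0801, 0.0779 and 0.0606). With the within-group mean taken per group, a statistic chosen after those values were seen, the exact permutation p ran from 0.00216 to 0.00433 over the 12 libraries left out. With each circRNA counted as detected or not, also chosen later, the exact permutation p was 0.0801.

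Cirrhosis-PTH was compared with Cirrhosis to ask what oral Pien Tze Huang changed on top of CCl4. The circRNAs with the smallest p were lower in Cirrhosis-PTH. That of Wac, which encodes a WW-domain adaptor protein, had 36 reads and 1.14 ± 1.17 CPM in Cirrhosis (mean ± SD, n = 6) and 0 reads in all 6 Cirrhosis-PTH libraries. The Pvt1 circRNA stood at 5.60 ± 4.11 CPM in Cirrhosis and 1.29 ± 0.763 in Cirrhosis-PTH, and the Adgre1 circRNA of exons 6 to 7 at 0.727 ± 0.465 and 0.061 ± 0.083 CPM. The circRNA of the helicase gene Ascc3 stood at 1.52 ± 0.572 and 0.450 ± 0.556 CPM, and that of the transcriptional repressor gene Etv6 at 1.05 ± 0.945 and 0.141 ± 0.286 (0.673 in Cirrhosis without Cirrhosis 5).

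No single circRNA passed limma's test at an adjusted p of 0.05 in this comparison, against 34 with an unadjusted p under 0.05 (8 higher and 26 lower in Cirrhosis-PTH, 23.7 in all by chance). On the recovered reads edgeR called 1, with 24 under an unadjusted 0.05, and DESeq2 called 1, with 37. Both calls were the Wac circRNA (chromosome 18, 7901496 to 7906044, coding exons 4 to 6, 336 bp), with an adjusted p of 0.051 in limma, 0.0392 in edgeR and 0.0125 in DESeq2. Against a floor of 3 reads over the group it was at least 22.1-fold lower in Cirrhosis-PTH than in Cirrhosis, counting error only, and at least 13.2-fold without Cirrhosis-PTH 6, the deepest library of the group. Control had 6 Wac reads in 3 of 6 libraries. The smallest adjusted p ran from 0.00678 to 0.386 over 15 alternatives of tool and setting.

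The log2 difference of Pvt1 was -1.78 ± 0.59 and that of the Etv6 circRNA (chromosome 6, 134115220 to 134137417, 1 end at an annotated exon end) -2.20 ± 0.73. The Adgre1 circRNA of exons 6 to 7 differed by -1.88 ± 0.66, the Ascc3 circRNA (chromosome 10, 50748806 to 50767507, coding exons 31 to 36, 765 bp) by -2.05 ± 0.73 and the Fndc3a circRNA (chromosome 14, 72652016 to 72683771, exons 2 to 3, 5' UTR and coding, 214 bp) by -1.84 ± 0.67. All 5 had an adjusted p of 0.386 in limma and lay below the Cirrhosis mean in 6 of 6 Cirrhosis-PTH libraries. The Fndc3a circRNA stood at 0.666 ± 0.613 CPM in Cirrhosis and 0.034 ± 0.084 in Cirrhosis-PTH, where its 6 reads came from 1 library. For Wac and Snx5 every Cirrhosis-PTH library lay below every Cirrhosis library, 2 circRNAs where chance gives 1.03 (0.216%). The median log2 difference was -0.17 with 42.0% higher in Cirrhosis-PTH. Centring each library on the median of the 26 circRNAs detected in all 18 moved these to 0.34 and 63.9%.

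In Cirrhosis-PTH against Cirrhosis, 0 of the 13 lists passed camera. All 3 macrophage and Kupffer cell circRNAs were lower, with camera's adjusted p = 0.0897 (0.757 with an estimated correlation). The Adgre1 circRNA of exons 6 to 7 passed adjusted over that list alone (limma adjusted p = 0.0132), and Mertk stood at 0.843 ± 0.648 CPM in Cirrhosis and 0.215 ± 0.140 in Cirrhosis-PTH. The 3 summed to 3.07 ± 2.34 CPM in Cirrhosis and 0.788 ± 0.420 in Cirrhosis-PTH, from 115 and 47 reads (exact permutation p = 0.0281, 2-sided). Leaving out 1 library moved that exact permutation p between 0.00433 and 0.0563, and it passed 0.05 without Cirrhosis 2, 4 or 5 (0.0563 each), without Cirrhosis-PTH 4 (0.0563) or without Cirrhosis-PTH 6 (0.0519). All 5 cell cycle circRNAs were lower, with that of the DNA repair gene Brca2 at 0.703 ± 0.738 and 0.214 ± 0.405 CPM (0.457 without Cirrhosis 4 and 0.0509 without Cirrhosis-PTH 6) and that of Fancl at 0.800 ± 0.871 (0.521 without Cirrhosis 5) and 0.429 ± 0.499. Lower members were 8 of 10 in the signalling list, 10 of 16 among chromatin regulators, 3 of 4 among secreted plasma proteins, 4 of 7 in carbohydrate and in xenobiotic metabolism, and 2 of 3 among hepatocyte markers. Higher members were 7 of 12 in lipid metabolism, 5 of 8 in amino acid metabolism, 4 of 5 in bile acid transport, 8 of 12 among ubiquitin ligases and 17 of 31 among widely studied hosts. These 12 lists had camera adjusted p values of 0.54 to 0.808. Camera's direction was up for carbohydrate and xenobiotic metabolism and for hepatocyte markers although their medians (-0.10, -0.11 and -0.11) and means were negative. It was also up for widely studied hosts, with a median of 0.08 and a mean of -0.01. Camera sets a list against the other circRNAs, and the median over all 474 was -0.17.

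The profiles of Cirrhosis-PTH and Cirrhosis lay apart by 0.946 (36.6 between and 35.6 within groups; exact permutation p = 0.00216, adjusted 0.00325, 1-sided). Leaving out any 1 of the 6 Cirrhosis-PTH libraries ended the call, at exact permutation p values from 0.119 without Cirrhosis-PTH 6 to 0.303 without Cirrhosis-PTH 2. With the within-group mean per group, chosen after these values were seen, the exact permutation p ran from 0.00216 to 0.0433. With circRNAs as detected or not it was 0.0519 (exact permutation, chosen later).

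Cirrhosis-PTH was compared with Control to ask what remained apart from corn oil under CCl4 with Pien Tze Huang. The circRNAs with the smallest p were lower in Cirrhosis-PTH except that of Rock1, at 0.190 ± 0.247 CPM in Control and 1.14 ± 0.815 in Cirrhosis-PTH (mean ± SD, n = 6). That of Pabpn1, the nuclear poly(A)-binding protein gene, stood at 0.928 ± 0.589 and 0.051 ± 0.080 CPM, that of the corepressor gene Tle1 at 1.15 ± 1.25 (0.714 without Control 1) and 0.088 ± 0.215, and that of the threonine aspartase gene Tasp1 at 0.920 ± 0.626 and 0.112 ± 0.178. The circRNA of Hpn, which encodes hepsin, a serine protease of the hepatocyte surface, stood at 1.08 ± 1.14 and 0.193 ± 0.421 CPM (0.0218 in Cirrhosis-PTH without Cirrhosis-PTH 1).

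No single circRNA passed limma's test at an adjusted p of 0.05 in this comparison, against 25 with an unadjusted p under 0.05 (7 higher and 18 lower, 23.7 in all by chance), and edgeR and DESeq2 called 0 each, with 20 and 28 under an unadjusted 0.05. The Pabpn1 circRNA (chromosome 14, 54897121 to 54897272, coding exon 6, 152 bp) had the smallest adjusted p in limma, 0.506, with a log2 difference of -2.32 ± 0.71 and 6 of 6 Cirrhosis-PTH libraries below the Control mean. It had 30 reads in Control and 2 in Cirrhosis-PTH, a pooled ratio of 27.7 (exact 95% interval 7.03 to 239, counting error only; 16.6 without Cirrhosis-PTH 6, 49.5 without Cirrhosis-PTH 3 and 51.1 without Cirrhosis-PTH 1). The circRNAs of Tle1 (chromosome 4, 72169122 to 72170770, coding exons 5 to 6) and Tasp1 (chromosome 2, 140042094 to 140057499, exons 2 to 4, 5' UTR and coding) both differed by -2.13 (SE 0.71 and 0.73), with limma's adjusted p = 0.587. Tle1 had 33 reads in Control and 3 in Cirrhosis-PTH, a pooled ratio of 20.3 (6.37 to 104; 12.2 without Cirrhosis-PTH 6), with all 3 from Cirrhosis-PTH 1. Rock1 differed by 1.99 ± 0.71 (limma adjusted p = 0.623) and lay above the Control mean in 6 of 6 Cirrhosis-PTH libraries. The circRNA of the Golgi protein gene Dym (chromosome 18, 75114790 to 75126919, coding exons 9 to 13) had 18 reads in Control and 2 in Cirrhosis-PTH, a pooled ratio of 16.6 (3.98 to 148), with both from Cirrhosis-PTH 6. It differed by -1.69 ± 0.65 and that of Hpn (chromosome 7, 31108965 to 31109192, coding exons 3 to 4) by -1.90 ± 0.73, both with an adjusted p of 0.688 in limma. Every Cirrhosis-PTH library lay below every Control library for Pabpn1 and for Fbxo8 (chromosome 8, 56564558 to 56569410, named after its values were seen), 2 circRNAs where chance gives 1.03 (0.216%).

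In Cirrhosis-PTH against Control, 0 of the 13 lists passed camera, with adjusted p values of 0.535 to 0.969, and no member passed limma over all circRNAs or adjusted over its list alone. Of the macrophage circRNAs 1 of 3 was higher, and they summed to 0.545 ± 0.348 CPM in Control and 0.788 ± 0.420 in Cirrhosis-PTH (exact permutation p = 0.299, 2-sided). Higher members were 9 of 12 in lipid metabolism, with Acaca at 0.276 ± 0.327 CPM in Control and 1.0 ± 0.874 in Cirrhosis-PTH, 23 of 31 among widely studied hosts, 8 of 12 among ubiquitin ligases and 3 of 3 hepatocyte markers. They were 4 of 8 in amino acid metabolism, 4 of 7 in carbohydrate metabolism, 3 of 5 in bile acid transport, 6 of 10 in signalling and 3 of 5 in cell cycle. Lower members were 6 of 7 in xenobiotic metabolism, 3 of 4 among secreted plasma proteins and 10 of 16 among chromatin regulators. Plasma protein circRNAs of Mug1 and Mug2 lie in a family of near-identical genes and are uncertain. Median and mean log2 difference were of opposite sign for macrophage markers (-0.07 and 0.32, camera up), carbohydrate metabolism (0.03 and -0.10, camera down) and bile acid transport (0.06 and -0.06, camera down). The profiles lay apart by 0.410 (exact permutation p = 0.134, 1-sided). After thinning every library to 794 reads or after quantile normalization, both chosen after the data were seen, the exact permutation p was 0.00216, and with the planned Spearman distance it was 0.0043.

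The design also asks whether Pien Tze Huang moved circRNAs back towards Control. Across the 474 circRNAs, which are not independent replicates, the log2 differences of Cirrhosis against Control and of Cirrhosis-PTH against Cirrhosis had a correlation of -0.621. Unchanged groups that share the Cirrhosis libraries gave -0.499 on average, and 0.104 of the 1000 simulated draws were as negative. The covariance was -0.390 against a simulated -0.223, and 0 of the 1000 draws were as negative. The draws gave all groups the same spread, while the real Cirrhosis libraries were the most spread. Their mean distances to their own group were 34.1 to 42.0, against 31.2 to 38.6 in Control and 31.8 to 35.3 in Cirrhosis-PTH. A wider shared group makes this covariance more negative with no effect, so the draws overstate the evidence. With the Cirrhosis libraries split into 3 and 3, so that the comparisons shared none, the correlation averaged -0.163 over 20 splits (range -0.212 to -0.115), and 0.007 of the draws were as negative. Of the 474 circRNAs 71.1% had opposite signs, against 66.8% in the draws. Pvt1, with 1.81 in the one comparison and -1.78 in the other, and Snx5, with 2.40 and -2.0, were among them. Both were picked for small p in comparisons that use the Cirrhosis libraries. Such picking favours opposite signs with no effect, so they are no evidence of a return. No circRNA passed limma in Cirrhosis against Control, so the share of passing circRNAs with the opposite sign could not be given.

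**Figure D3:**
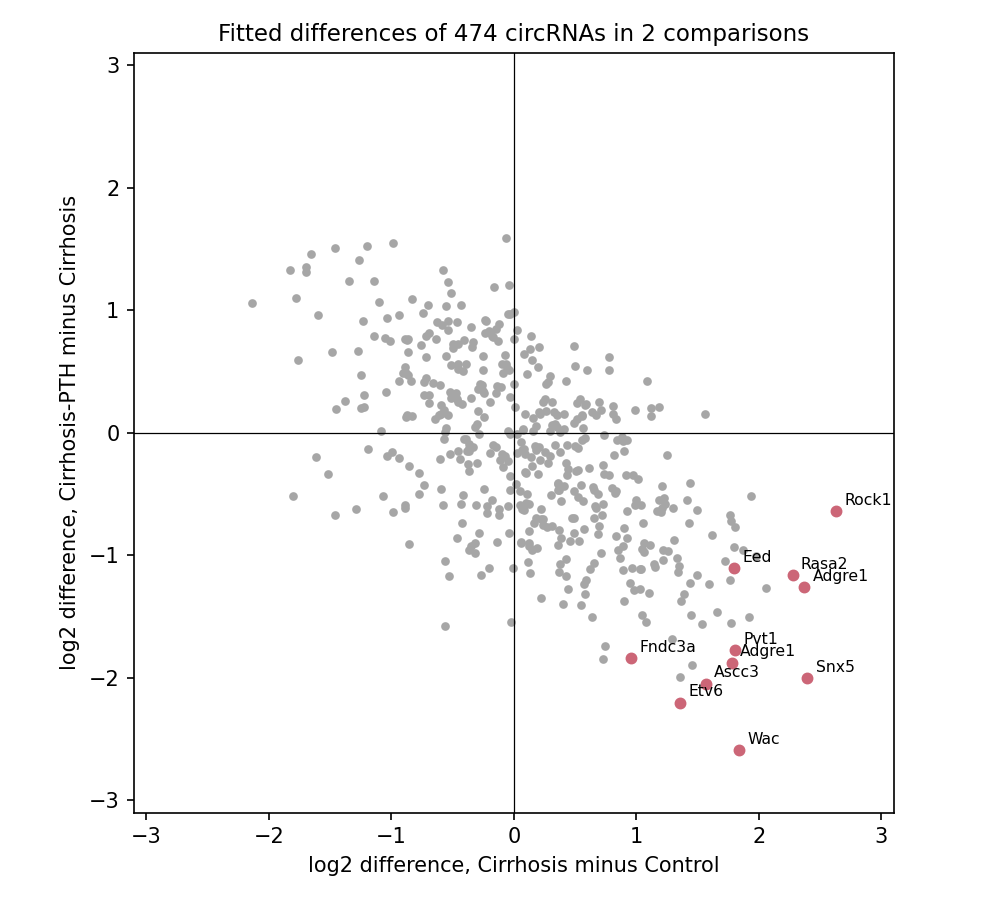
Fitted log2 difference of each of the 474 circRNAs in Cirrhosis minus Control (x axis) and Cirrhosis-PTH minus Cirrhosis (y axis), grey points, with the circRNAs of smallest p in red and labelled by host gene. The labelled circRNAs lie at the lower right. They were picked for small p in comparisons that share the Cirrhosis libraries, which favours opposite signs. The correlation of -0.621 includes the part that the shared Cirrhosis libraries give with no effect.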

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

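The tests of the macrophage-list sums and shares, the split of the Cirrhosis libraries, the profile tests after centring and the other splits in edgeR were chosen after the results they bear on were seen.

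The circRNAs of the macrophage list, from Adgre1 and Mertk, stood higher on average in Cirrhosis than in Control and lower in Cirrhosis-PTH than in Cirrhosis, but Cirrhosis 6 had 1 such read (0.184 CPM, 0.045% of its reads), below 5 of 6 Control libraries. An effect of the log scale at few reads is argued against by their summed CPM on the linear scale (unadjusted exact permutation p = 0.013). A change in the yield of all circRNAs is argued against only weakly by their share of recovered reads. That share was 0.263% in Control, 0.960% in Cirrhosis and 0.322% in Cirrhosis-PTH. Its exact permutation p values, 0.0281 and 0.039, were not adjusted over the 3 pairs. With 1 library left out they reached 0.0563 (without Control 2 or Cirrhosis 2, 4 or 5) and 0.0779 (without Cirrhosis 2, 4 or 5). The latter comparison was above 0.05 too without Cirrhosis 3 or Cirrhosis-PTH 1, 2, 4, 5 or 6. As a hypothesis, a larger macrophage share of the liver under CCl4 and a smaller one with Pien Tze Huang may contribute, but it rests on 3 circRNAs of 2 hosts and 115 Cirrhosis reads. A change in how these transcripts are circularized, library batches and chance stay open. Camera's call (adjusted p = 0.0203) was lost with an estimated correlation (adjusted p = 0.388) and with the title number as replicate block (adjusted p = 0.13). In addition, 9 of the 100 splits of the Cirrhosis and Control libraries gave at least as many lists past camera's threshold as the real 1 (highest other 2).

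The changes in Cirrhosis against Control and in Cirrhosis-PTH against Cirrhosis were opposite in 71.1% of circRNAs, but their correlation of -0.621 lay within the draws with no effect (mean -0.499, 0.104 of draws as low, 66.8% opposite), which share the Cirrhosis libraries too. The shared libraries as the whole cause are argued against only weakly by the correlation with those libraries split, -0.163. A value as low came in 0.007 of the simulated draws, counting low values only. These draws gave all groups the same spread, while the real Cirrhosis libraries were the most spread. With the same limit, the split correlation stayed negative without Cirrhosis 6, at -0.129 (0.044 of draws as low). It was -0.16 after quantile normalization (0.01 of draws as low). The value without Cirrhosis 6 does not decide whether that library contributed, and the scaling of libraries as the cause is argued against only weakly. A partial return of the Cirrhosis profile towards Control under Pien Tze Huang is a hypothesis that would give such a sign. A handling or sequencing difference that set the Cirrhosis libraries apart from both other groups would give it too, and stays open because the labels name no batch.

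The profiles of Cirrhosis lay apart from Control and from Cirrhosis-PTH although no single circRNA passed limma. The scaling of libraries as the cause is argued against by the exact permutation p after centring, 0.00433 and 0.0173, and read depth by that after thinning to 794 reads, 0.00216 for both, although Cirrhosis-PTH against Control (0.134 with the planned statistic) passed too, at 0.0173 after centring and 0.00216 after thinning, so neither tells the 3 pairs apart. As a hypothesis, small changes in many circRNAs, with CCl4 in the one comparison and with Pien Tze Huang in the other, may account for the separations. They weakened with the planned statistic when Control 1, 2 or 7 (exact permutation p = 0.0801, 0.0779 and 0.0606) or any Cirrhosis-PTH library (0.119 to 0.303) was left out, and with circRNAs as detected or not (0.0801 and 0.0519). The planned statistic pools within-group pairs, so leaving out a library also gives the other group more weight. With the within-group mean per group, chosen later, the left-out exact permutation p ran from 0.00216 to 0.00433 and from 0.00216 to 0.0433. As a ratio of squared distances, also chosen later, it reached 0.0584 in Cirrhosis-PTH against Cirrhosis. A batch that follows the groups stays open.

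Other splits of the libraries, 100 per comparison with the real one among them, were fitted in the same way with limma, and with edgeR. For Cirrhosis against Control, 1 split had as many circRNAs with an unadjusted p under 0.05, the real one with 58 (highest other 42). In edgeR too 1 split had as many, the real one with 29 (highest other 24). No other split drawn reached either count, which argues against chance only as far as 100 splits can tell. The count ran from 29 to 78 over the alternatives, and a batch that follows the groups stays open. For Cirrhosis-PTH against Cirrhosis 8 splits reached the real 34 (highest other 42) and for Cirrhosis-PTH against Control 19 reached the real 25 (highest other 41), with 8 and 9 splits in edgeR for the real 24 and 20 (highest other 30 and 24), so chance cannot be excluded. The real adjusted counts were 0 in limma (58, 34 and 25 unadjusted) with a highest other of 1, 0 and 1, and a count of 0 is reached by all 100 splits whatever the data, so these say nothing about chance. In edgeR and DESeq2 the adjusted counts were 0 and 1, 1 and 1, and 0 and 0. The 0 lists past camera in the comparisons of Cirrhosis-PTH (highest other 1 in each) say nothing about chance for the same reason.

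Of 69 groups of 6 values examined, 12 held a value far from the rest of its group. The nominal rate would give 3.5, but it assumes normal and independent values. Values at few reads and related library measures are neither, so an excess over chance is not shown. Cirrhosis-PTH 6 had a total behind the CPM of 29164326, 8431 recovered reads and 20.8 reads per detected circRNA. Cirrhosis 6 had 9.95 reads per detected circRNA, the highest of its group, with the fewest circRNAs detected. In Control 6 the 10 most abundant circRNAs took 13.1% of reads, the lowest share in Control. Among named circRNAs, Etv6 (chromosome 6, 134115220 to 134137417) stood at 0.715 CPM in Cirrhosis-PTH 5, Fndc3a at 0.206 in Cirrhosis-PTH 6, Dym (exons 9 to 13) at 0.069 in Cirrhosis-PTH 6, and Tle1 and Hpn at 0.526 and 1.05 in Cirrhosis-PTH 1, each above the rest of the group. The Adgre1 circRNA of exons 6 to 7 was at 0 in Cirrhosis 6, and Dym at 0 in Control 2, each below the rest.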

How the results depend on the processing

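Of the alternatives below, edgeR with the totals behind the CPM, the left-out pair, thinning, other scalings or left-out libraries in list tests, left-out libraries for summed CPM, and every distance setting except Spearman and the planned left-out libraries were chosen after the data were seen.

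All 28 differences of the circRNAs of smallest p kept their direction over the 747 alternative values, and 9 values from 2 circRNAs moved past the threshold. These circRNAs were picked for small p in the same libraries, so the kept direction says little. With limma, Cirrhosis against Control had 2 circRNAs past the threshold under median centring (Hnrnpu and Ube2g2, adjusted p 0.0272) and 1 without a trend (Rock1, 0.0372), and DESeq2 called 1 (Ube2g2, 0.0249). With 1 library left out limma called 0 to 1, the 1 being Rock1 without Control 3 (0.0488). In Cirrhosis-PTH against Cirrhosis, Wac was the 1 call of limma without a trend (0.0487), of edgeR with TMM (0.0392) or with the totals behind the CPM (0.00678), and of DESeq2 (0.0125). With 1 library left out limma called 0 to 1, Wac without Cirrhosis 1, 2 or 3 (adjusted p 0.0184, 0.0363 and 0.028). Cirrhosis-PTH against Control had 0 calls with limma under every alternative, 0 with edgeR and 0 with DESeq2, beside 13 to 36 unadjusted. Over 15 alternatives the smallest adjusted p ran over 0.0249 to 0.412, 0.00678 to 0.386 and 0.0534 to 0.636, and over the left-out libraries over 0.0488 to 0.185, 0.0184 to 0.188 and 0.2 to 0.795. Median centring moved the share higher to 28.9%, 63.9% and 46.2% from 56.1%, 42.0% and 49.8%. The filter of at least 6 libraries removes nothing, so leaving it out tests nothing.

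Camera called 0 lists in Cirrhosis against Control with an estimated correlation (macrophage list adjusted p 0.388) and 0 with 1 circRNA per host, where that list has 2 members and is too small to test. With 1 library left out it called 0 to 1, with 0 without Control 2, Cirrhosis 2, 4 or 5. In Cirrhosis-PTH against Cirrhosis it called 1, the macrophage list, after quantile normalization (0.0261) and without Cirrhosis 6 and Cirrhosis-PTH 4 (0.0129), and 0 to 1 with 1 library left out, the 1 without Cirrhosis 6 (0.00541). Its adjusted p ran from 0.000918 to 0.388 in Cirrhosis against Control and from 0.00541 to 0.757 in Cirrhosis-PTH against Cirrhosis.

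No label says that the numbers in the titles pair the libraries, and no correlation of same-numbered libraries passed 0.1 (-0.057 to 0.082). In Cirrhosis against Control, though, all 4 were positive and 3 of 4 libraries were closest to their own number (exact permutation p = 0.025 over every assignment of numbers, a test chosen after the correlations were seen, against 0.7139 and 0.6889 in the other comparisons), so a pairing there stays open. As a replicate block they left 0 circRNAs past limma's threshold in each comparison (38, 32 and 27 unadjusted) and 0 lists, with 0.13 for the macrophage list in Cirrhosis against Control.

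Differences in detected circRNAs, none past the threshold, changed sign readily. Counting from 4 pseudocounts gave 13.8, -32.0 and -18.2 in the order of the comparisons, thinning gave -16.5 for Cirrhosis-PTH against Control, and leaving out Cirrhosis 6 and Cirrhosis-PTH 4 gave 17.4 and -3.8 for the comparisons with Cirrhosis. With 1 library left out they ran from -19.0 to 17.4, from -16.9 to 16.6 and from -15.5 to 13.6, and the difference of summed CPM in Cirrhosis-PTH against Control ran from -31.2 to 18.6.

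The distance with 1 library left out ran from 0.889 to 2.16 in Cirrhosis against Control and from 0.222 to 1.72 in Cirrhosis-PTH against Cirrhosis. It missed the threshold with circRNAs as detected or not (0.167 and 0.254), and in Cirrhosis-PTH against Cirrhosis as a ratio of squared distances without Cirrhosis-PTH 2 (0.133). In Cirrhosis-PTH against Control it passed under Spearman distance (0.0267), centring (0.62), quantile normalization (0.72), thinning (0.493), without Cirrhosis 6 and Cirrhosis-PTH 4 (0.643) and without Cirrhosis-PTH 4 alone by the per-group mean (0.643) or the ratio (0.135). The cause of these changes was not tested. Of 175 group means above 0 of the 59 circRNAs looked at singly, 52 moved by over 1.5 times without the highest library of the group. The median value rests on 2 reads, and the effect of depth on single calls was not tested.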

Other observations

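The count of circRNAs that start at exon 2 was chosen for a test after it was seen, and the tests of introns and of shared hosts were set before their results.

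Exon 2 was a frequent first exon of the listed circRNAs. Of the 431 circRNAs with an intron on both sides, 171 (39.7%) started at exon 2 of their transcript, among them those of Ube3a, Rasa2, Fndc3a and Tasp1, and 3 of all listed circRNAs included the first exon. Random placement of the same number of exons in the same transcripts gave 64.8 on average and 93 at most over 10000 draws (permutation p = 0.0001, the smallest they can give). The introns that flank the circRNAs were long for their transcripts, with a median of 11000 bp against 2410 bp for the median intron, and a median percentile of 86.4 against 53.7 in random placements (permutation p = 0.0005, the smallest that 2000 draws can give). Since early introns tend to be long, the 260 circRNAs that start after exon 2, such as those of Rock1, Eed and Snx5, were also taken alone, at a median percentile of 81.1 against 51.5 at random (permutation p = 0.0005). Both are consistent with the hypothesis that long flanking introns favour back-splicing, which the table cannot test, since it lists only circRNAs found in 9 or more libraries.

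The hypothesis that circRNAs of 1 host gene vary together between libraries of a group was not borne out, but the test could not decide it. Over 67 pairs from 48 hosts, such as the pairs of Adgre1 and of Bckdhb, the mean within-group correlation was 0.0638, against 0.0752 in random pairs (permutation p = 0.6455). With a median of 2 reads per circRNA and library, counting noise pulls such correlations towards 0 and could hide a shared variation.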
